A study of Homo sapiens with 6 samples.

How the data were processed

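Total RNA from HPMEC, primary human lung microvascular endothelial cells, was made into miRNA libraries with ligated 3' and 5' adapters and unique molecular identifiers, from 1 ug of RNA with an integrity number of at least 7, and read as 100 bp pairs with a target of 10 to 25 M reads per sample, per the labels' protocols. Libraries were grouped as Ctrlsh or TENT2sh by their titles, 3 in each. The treatment text of the labels names the TENT2 shRNA for all 6 samples, so the group rests on the title and the genotype label.

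The authors deposited a table of RPM values for 2731 miRNA names. Each library sums to 1000000, so the values are shares of the reads assigned to miRNAs and carry no information on total miRNA output. The submitters' processing notes name GRCh38 and DESeq2 1.22.1. The aligner, the counting tool, the miRNA annotation and whether molecular identifiers were collapsed are not given in the sources used here. In 62 rows several miRNAs share 1 name (let-7a/7c, for example), and reads of these sequences cannot be told apart. The values of each library were whole multiples of 1 step within a tolerance of 0.01 step, which implies 11118142 to 17042713 reads per library. The smallest value listed was 2 steps, so the table does not list single reads, a 0 gives no upper limit, and no count-based test was run on it.

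The authors also deposited a table of their comparison. Its mean is a signal, the mean normalized count over libraries, and its fold changes and standard errors are on the log2 scale, per the file headers. The statistic is a score, and p-values and adjusted p-values came from DESeq2, per the file headers and the submitters' processing notes. The mean there was 0.975 times the mean of the reads implied by the RPM values after median-of-ratios scaling (median over the tested miRNAs, 10th to 90th percentile 0.833 to 1.09) and 0.497 times for miR-24-3p. For 77 miRNAs the authors' deposited table gave a mean above 0 while all RPM values were 0. The counts behind the authors' deposited table were therefore not those behind the RPM values, and the tables were not combined. The authors' deposited table gave a fold change but no p for 7 miRNAs, miR-24-3p among them.

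For the comparison, miRNAs with at least 1 RPM in at least 3 of the 6 libraries were kept. This left 461 of the 911 miRNAs above 0 in any library, with at least 98.6% of the RPM of each library. Values were tested as log2(RPM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Differences on this scale understate the change of miRNAs near 1 RPM. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 16 lists with at least 3 measured members. The lists were the let-7 family, let-7 from group II precursors, the miR-17~92 cluster and paralogues, the miR-15/16, miR-29, miR-30 and miR-181 families, the 14q32 cluster, mirtrons and other Drosha-independent miRNAs, endothelial-enriched and angiogenic, endothelial inflammation, endothelial-mesenchymal transition and fibrosis, p53 and senescence, and markers of epithelial, mesenchymal and blood cells. The hepatocyte list had only miR-122-5p measured and was not tested as a list. The arm comparison used limma on the log2 ratio of (5p RPM + 1) to (3p RPM + 1) in 103 hairpins, paired by name. Composition was compared with exact two-sided permutation tests (scipy 1.17.1, Python 3.11.15).

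Groups, tests, lists, alternatives and the rule for naming miRNAs were set before the data were examined, except where the text says that a choice came later. The rule took the 10 largest rises and falls past the threshold or, with none past it in a direction, the 5 smallest p-values in that direction. It also took the 10 most abundant miRNAs, up to 4 members per list with the smallest p, miR-122-5p and the let-7 family, and the 4 hairpins with the smallest p. miR-24-3p, miR-6866-5p and the miRNAs named for replicate 3 or for presence in 1 group fall outside it and were chosen after their values were seen. Coordinates come from GENCODE release 29 on GRCh38.

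Replicate numbers come from the titles. The numbers were taken to pair the libraries. Deviations from the group means over the 461 miRNAs had correlations of 0.577, 0.652 and 0.918 for numbers 1, 2 and 3. Only replicate 3 bears the pairing out: Ctrlsh 1 with TENT2sh 2 and Ctrlsh 2 with TENT2sh 1 gave higher values, 0.726 and 0.696. Because replicate 3 stands apart in both groups, libraries 1 and 2 deviate together whatever their pairing. For numbers 1 and 2 the pairing thus rests on the titles alone. The block fits, the counts of pairs and the splits that part pairs carry this limit. No 2 libraries agreed within sampling noise, and all 6 were used as separate samples.

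The tests were tried on simulated data built from the 461 miRNAs, with 20 datasets. Single changes were planted only in miRNAs averaging above about 10 RPM, so the shares called do not cover rarer miRNAs. Without the replicate block 4.5% of 1.5-fold changes, 32.8% of 2-fold changes and 74% of 4-fold changes were called, with 0 false calls. With the block all were called, with 2.7 false calls per dataset. A shift of the let-7 list by -0.5 on the log2 scale was found in 20 of 20 datasets in both fits. The simulated noise was independent between miRNAs, while the real let-7 list had an estimated correlation of 0.28, or 0.55 with the block. The simulation may therefore overstate how readily such a shift would be found. In the real values the median half-width of the 95% interval was 1.58-fold without the block and 1.20-fold with it. Alternatives were other pseudocounts, filters and scalings, other variance settings, array weights, the replicate block, each library left out, and other set tests. The contrast of replicate 3 with replicates 1 and 2, treating the replicate 3 libraries as a batch, leaving both out, and set tests with the block were added after seeing the data.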

Results

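Small RNAs were sequenced from human primary lung microvascular endothelial cells (HPMEC) carrying an shRNA against TENT2 (TENT2sh) or a control shRNA (Ctrlsh), with 3 libraries per group. TENT2 (also called GLD2 or PAPD4) is a cytoplasmic nucleotidyltransferase known to add single nucleotides to the 3' ends of miRNAs and their precursors, such as miR-122 in liver. The series compares the 2 groups to ask what TENT2 knockdown does to the miRNA profile. The cells were at passage 4. Lentiviral transduction lasted 36 h, followed by 6 h without serum and 24 h with PBS. TENT2 mRNA is not measured by a miRNA library, so the knockdown could not be checked in these values. The labels do not say that the replicates came from separate cultures or donors, so p-values measure the spread between these samples, which may be technical.

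Levels are in RPM, reads per 1000000 reads assigned to miRNAs. The spacing of the values in each library implied 11118142 miRNA reads in Ctrlsh 1, 13390476 in Ctrlsh 2 and 16736421 in Ctrlsh 3, and 16188999, 15431887 and 17042713 in TENT2sh 1, 2 and 3. The number of miRNAs at 1 RPM or more was 452.7 ± 9.02 in Ctrlsh and 457 ± 17.6 in TENT2sh (SD, n = 3; exact two-sided permutation p = 0.9, where 3 against 3 cannot go below 0.1). The 10 most abundant miRNAs of each library held 82.0% ± 0.705 of the reads in Ctrlsh and 81.6% ± 0.202 in TENT2sh (SD, n = 3; exact two-sided permutation p = 0.5).

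In both groups the miR-126 hairpin, typical of endothelial cells, held first place. miR-126-3p, an endothelial miRNA that maintains vascular integrity, stood at 341323 ± 12171 RPM in Ctrlsh and 333596 ± 7821 RPM in TENT2sh (SD, n = 3), a ratio of 0.978 with a 95% interval of 0.868 to 1.10. Its precursor lies in an intron of EGFL7 (GRCh38, chromosome 9, 136670602 to 136670686, plus strand). miR-126-5p followed at 141734 ± 52646 and 140847 ± 43754 RPM, and let-7a/7c at 82584 ± 25956 and 81843 ± 22368 RPM (SD, n = 3). The other members of the top 10 were let-7f, miR-16-5p, let-7b, let-7i, miR-29a-3p, let-7g and miR-21-5p, and limma gave each of the 10 an adjusted p of 0.999.

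No miRNA passed the threshold between TENT2sh and Ctrlsh. Of 461 miRNAs tested with limma on log2(RPM + 1), 0 had a Benjamini-Hochberg adjusted p under 0.05 and 2 had an unadjusted p under 0.05, against 23.1 from chance. With the replicate number as a block, limma again called 0, but 51 had an unadjusted p under 0.05, 36 of them higher in TENT2sh. Differences were small: 446 of the 461 lay within 0.5 of 0 on the log2 scale, and the median size was 0.11. Among the 107 miRNAs averaging at least 100 RPM, the 95% interval of the difference lay within 1.5-fold for 41 without the block and for all 107 with it.

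**Figure D1:**
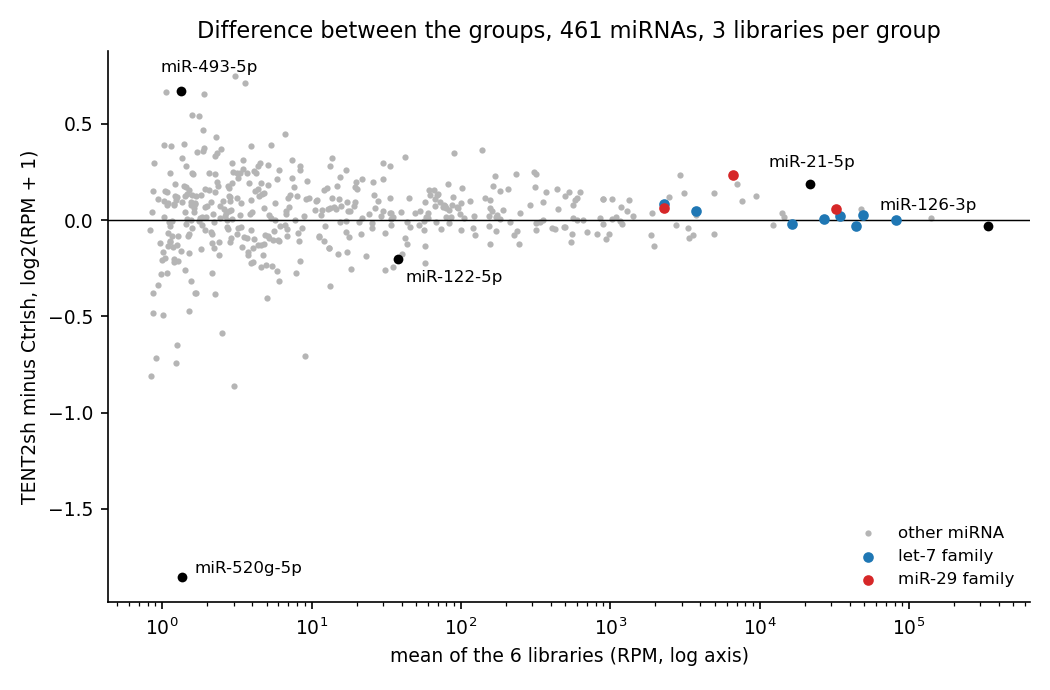
Each point is 1 of 461 miRNAs, with its mean over the 6 libraries on a log axis (RPM) and TENT2sh minus Ctrlsh on the log2(RPM + 1) scale. Abundant miRNAs such as miR-126-3p, the let-7 family (blue) and the miR-29 family (red) lie near 0, the scatter widens toward 1 RPM, and miR-520g-5p, listed at 0 in TENT2sh, lies lowest.

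The miRNA closest to the threshold was miR-520g-5p, from the primate-specific chromosome 19 miRNA cluster (C19MC; MIR520G, GRCh38, chromosome 19, 53722166 to 53722255, plus strand, in no annotated gene on that strand). It was listed at 2.79, 3.58 and 1.73 RPM in Ctrlsh 1, 2 and 3 and at 0 in all 3 TENT2sh libraries, with a limma adjusted p of 0.081 (0.063 with the replicate block). The call was made with a pseudocount of 0.5 (adjusted p = 0.047), with array weights (adjusted p = 0.00086) and with the replicate 3 libraries as a batch term (adjusted p = 0.017), and it was not made in the other settings that kept this miRNA past the filter, where the adjusted p reached 0.549. A 0 in this table is not always absence: the abundant endothelial miR-24-3p was listed at 0 in replicates 1 and 2 of both groups and at 12645 and 13926 RPM in Ctrlsh 3 and TENT2sh 3.

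The other miRNAs with the smallest p in each direction did not pass the threshold (limma adjusted p = 0.999 for each). On the higher side in TENT2sh were miR-493-5p, miR-3614-3p, miR-1260a/1260b, miR-1246 and miR-196b-5p. miR-493-5p, from the imprinted 14q32 cluster (MIR493, GRCh38, chromosome 14, 100869060 to 100869148, plus strand, intron of the lincRNA AL117190.1), measured 0.807 ± 0.129 RPM in Ctrlsh and 1.88 ± 0.249 RPM in TENT2sh (SD, n = 3), a log2 difference of 0.67 ± 0.16 (SE). miR-1246 measured 121 ± 9.60 and 157 ± 23.7 RPM, and miR-196b-5p, encoded in the HOXA cluster, 79.1 ± 5.41 and 101.5 ± 14.2 RPM (SD, n = 3). On the lower side, besides miR-520g-5p, were miR-4485-3p, miR-382-3p, miR-496 and miR-4766-5p. miR-382-3p measured 5.90 ± 0.857 RPM in Ctrlsh and 4.21 ± 0.684 RPM in TENT2sh (SD, n = 3), and miR-4485-3p was listed at 1.53, 0.896 and 1.43 RPM in Ctrlsh and at 1.17, 0 and 0 RPM in TENT2sh.

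The levels of the let-7 family and miR-122, on which TENT2 is known to act, gave no difference past the threshold. Only a level per miRNA name was available, so nucleotides added to 3' ends could not be examined. Of 8 let-7 rows, 6 had a positive log2 difference and 2 a negative one, with a median of 0.015 that became -0.040 under median-of-ratios scaling and 0 under quantile normalization (camera adjusted p = 0.944). The 6 rows listed as from group II precursors, whose maturation in other cells uses mono-uridylation, had a median of 0.024, which became -0.031 under median-of-ratios scaling (camera adjusted p = 0.928). This list leaves out the shared let-7a/7c row, so it need not hold every group II product. let-7f measured 48648 ± 850.0 RPM in Ctrlsh and 49485 ± 1105 RPM in TENT2sh (SD, n = 3), a log2 difference of 0.02 ± 0.08 (SE, limma adjusted p = 0.999). let-7i measured 34268 ± 960 and 34808 ± 262 RPM, and miR-98-5p 2217 ± 189 and 2346 ± 160 RPM (SD, n = 3). miR-122-5p, abundant in hepatocytes (MIR122, GRCh38, chromosome 18, 58451074 to 58451158, plus strand, overlapping an exon of the lincRNA MIR122HG), measured 40.8 ± 21.4 RPM in Ctrlsh and 34.4 ± 14.3 RPM in TENT2sh (SD, n = 3). Its log2 difference was -0.20 ± 0.44 (SE, limma adjusted p = 0.999), or ± 0.15 with the replicate block, and its 95% interval ran from 0.409-fold to 1.85-fold.

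The list of miRNAs tied to endothelial-mesenchymal transition and fibrosis had the highest median of the 16 lists tested, though not under quantile normalization or without the most abundant miRNA. Of its 15 measured members, 12 had a positive difference, with a median of 0.11, and the list did not pass (camera adjusted p = 0.928, or 0.963 with an estimated correlation). The median became 0.06 under median-of-ratios scaling and ran from 0.0051 to 0.157 over all settings. miR-21-5p, known for promoting fibrosis (MIR21, GRCh38, chromosome 17, 59841266 to 59841337, plus strand, overlapping an exon of VMP1), measured 20222 ± 2128 RPM in Ctrlsh and 23037 ± 2380 RPM in TENT2sh (SD, n = 3), higher in 3 of 3 pairs of same-numbered libraries, with a log2 difference of 0.19 ± 0.13 (SE, limma adjusted p = 0.999). miR-29b-3p, which targets collagen mRNAs and so goes against the list's name, measured 6128 ± 1869 and 7174 ± 2073 RPM (SD, n = 3), a log2 difference of 0.23 ± 0.28 (SE, limma adjusted p = 0.999), also higher in 3 of 3 pairs. The list also holds miR-29a-3p and miR-29c-3p of the same family, so it mixes miRNAs of opposite roles. Its median thus gives no direction for transition or fibrosis. Over all settings the log2 difference of miR-29b-3p ran from 0.0051 to 0.47. With the replicate 3 libraries as a batch term this list was called (camera adjusted p = 0.032), as was miR-29b-3p (limma adjusted p = 0.036), and without replicate 3 in both groups the list was called too (camera adjusted p = 0.013). With the replicate block camera did not call it (adjusted p = 0.074, or 0.800 with an estimated correlation), while fry did (adjusted p = 0.026). Adjusted over the list alone, 0 of the 15 members passed without the block and 1, miR-29b-3p, with it (limma adjusted p = 0.023).

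Lists of other endothelial functions did not pass either. Over all 461 miRNAs 284 had a positive difference and the median was 0.04 (-0.01 under median-of-ratios scaling), so list medians near that value do not stand out from the general shift. The endothelial-enriched and angiogenic list had 15 of 20 members positive (median 0.09) and the endothelial inflammation list 13 of 17 (median 0.08, camera adjusted p = 0.928 for both). Under median-of-ratios scaling these medians became 0.03 and 0.02. In the first, miR-23a/23b measured 2724 ± 1150 RPM in Ctrlsh and 3175 ± 1213 RPM in TENT2sh (SD, n = 3), miR-10a-5p 2948 ± 574 and 3238 ± 594 RPM, and miR-100-5p 284 ± 107 and 331 ± 98.97 RPM (SD, n = 3). In the second, miR-155-5p measured 594 ± 121 and 652 ± 90.7 RPM (SD, n = 3). The p53 and senescence list had 8 of 10 positive (median 0.06, but 0.01 under median-of-ratios scaling and 0.002 under quantile normalization). The miR-15/16 family had 5 of 7 positive (median 0.05, but 0.0002 under median-of-ratios scaling and 0.06 under quantile normalization) and the 14q32 cluster 35 of 53 (median 0.04, but -0.01 under median-of-ratios scaling). The miR-17~92 cluster and paralogues had 8 of 13 positive (median 0.04, but -0.02 under median-of-ratios scaling), the miR-29 family 3 of 3 (median 0.06, but -0.05 under quantile normalization) and mirtrons and other Drosha-independent miRNAs 4 of 7 (median 0.05, but -0.01 under median-of-ratios scaling). In the miR-30 family 1 of 4 rows was positive (median -0.03), and in the miR-181 family 1 of 4 (median -0.07). Camera gave these 8 lists an adjusted p of 0.928 each, and with an estimated correlation it gave all 16 lists 0.963. Adjusted over the list alone, limma called 0 members in each of the 16 lists. With the replicate block it called 1 member of the miR-29 family, miR-29b-3p (adjusted p = 0.0047), and fry then called the family (adjusted p = 0.026) where camera with the block did not (adjusted p = 0.130, or 0.800 with an estimated correlation). All members of this family are also in the list of endothelial-mesenchymal transition and fibrosis.

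**Figure D2:**
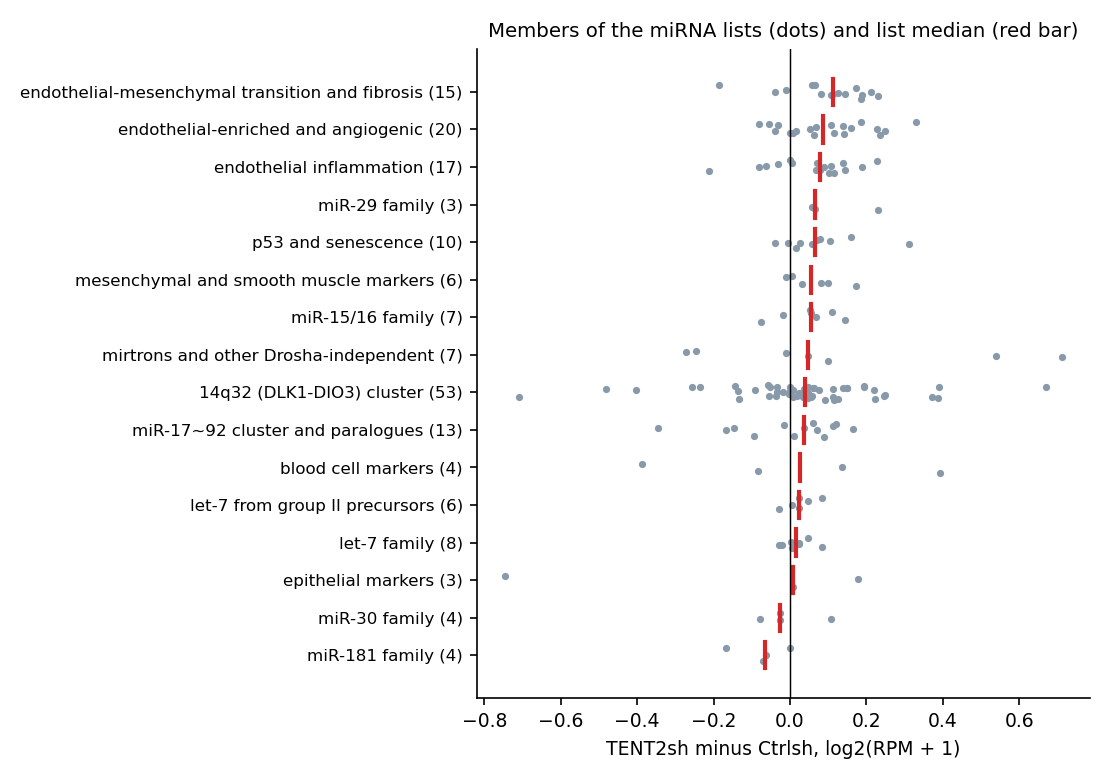
Dots are the tested members of each of the 16 lists (number in brackets), placed by TENT2sh minus Ctrlsh on the log2(RPM + 1) scale, and red bars are list medians. Medians run from -0.07 in the miR-181 family to 0.11 in the list of endothelial-mesenchymal transition and fibrosis, and 7 of the 16 change sign or reach 0 under another scaling.

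Markers of other cell types were listed at low levels in both groups. Summed over their lists, epithelial markers held 7.98 ± 1.24 RPM in Ctrlsh and 8.42 ± 2.29 RPM in TENT2sh, blood cell markers 7.06 ± 2.17 and 6.59 ± 1.28 RPM, and mesenchymal and smooth muscle markers 119 ± 3.76 and 126 ± 6.37 RPM (SD, n = 3). The hepatocyte list held 40.8 ± 21.4 and 34.4 ± 14.3 RPM (SD, n = 3). Only 3 of 11 epithelial, 4 of 11 blood cell and 6 of 12 mesenchymal rows passed the filter. A listed 0 gives no upper limit, so low sums need not mean low levels. The endothelial-enriched list held 515228 ± 74088 and 508920 ± 61907 RPM (SD, n = 3). None of the 3 marker lists that were tested passed (camera adjusted p = 0.928 for the epithelial list with 2 of 3 members positive and for the mesenchymal list with 5 of 6, and 0.944 for the blood cell list with 2 of 4). The medians were 0.01, 0.06 and 0.03 in that order, the epithelial one becoming -0.03 under median-of-ratios scaling. Camera ranked the epithelial, blood cell, miR-17~92 and mirtron lists downward although their medians were positive, and the means of the epithelial and miR-17~92 lists were -0.19 and -0.01.

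The choice between the 5p and 3p arms of a hairpin did not differ past the threshold. Of 103 hairpins with both arms measured, 0 had an adjusted p under 0.05 in limma on the log2 ratio of 5p to 3p, and 0 had an unadjusted p under 0.05. With the replicate block 0 passed (lowest limma adjusted p = 0.170). Of the 103, 13 then had an unadjusted p under 0.05, more than the 5% from chance. Without the block the smallest p-values were those of miR-142, miR-671, miR-4766 and miR-493 (limma adjusted p = 0.997 for each). The log2 ratio of miR-671 was 4.31 ± 0.16 in Ctrlsh and 4.82 ± 0.20 in TENT2sh, and that of miR-142, a blood cell hairpin near 1 RPM here, was 0.68 ± 0.14 and 0.16 ± 0.29 (SD, n = 3). With array weights 1 hairpin, miR-450b, was called (adjusted p = 0.017), which was named after its values were seen.

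The replicate 3 libraries of both groups stood apart from the other 4, and the spread they added was shared by the groups. The first principal component carried 79.7% of the variance and separated Ctrlsh 3 and TENT2sh 3 from the rest. In a contrast chosen after this separation was seen, which describes its extent and is no independent test of it, 294 of the 461 miRNAs passed between replicate 3 and replicates 1 and 2 in limma with group as a term, 136 higher and 158 lower in replicate 3, and across miRNAs, which are not independent replicates, the shifts of the 2 groups had a correlation of 0.918. miR-30b/30c averaged 448 RPM in the libraries of replicates 1 and 2 and 1777 RPM in those of replicate 3, and miR-99b-5p 2644 and 586 RPM.

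**Figure D3:**
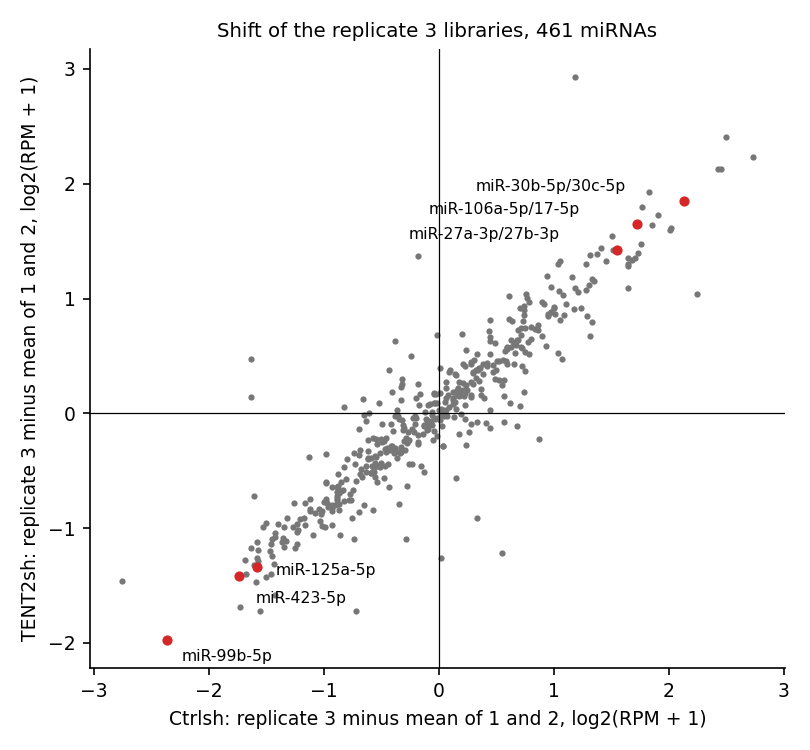
Each point is 1 of 461 miRNAs, with the shift of replicate 3 from the mean of replicates 1 and 2 on the log2(RPM + 1) scale in Ctrlsh (horizontal axis) and in TENT2sh (vertical axis). Most points follow the diagonal, and the red, named points are examples averaging at least 100 RPM, from miR-99b-5p at the lower left to miR-30b/30c at the upper right.

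The authors' deposited table of TENT2sh against Ctrlsh gave a log2 fold change for 988 miRNAs and an adjusted p for 981. At an adjusted p under 0.05 the authors' deposited table held 1 call, miR-6866-5p, with a DESeq2 log2 fold change of 5.94 and an adjusted p of 0.012. Its precursor overlaps an exon of CASC3 (GRCh38, chromosome 17, 40161933 to 40162001, plus strand). In the RPM values miR-6866-5p was listed at 0 in all 3 Ctrlsh libraries and at 0.865, 1.17 and 0.587 RPM in TENT2sh 1, 2 and 3, below the filter of the limma fit. With no filter limma tested 911 miRNAs, this one included, and called 0 (lowest adjusted p = 0.126), so the call was not shared in that fit either. The adjusted p was 1 for the other 980 miRNAs of the authors' deposited table, and 7 miRNAs of that table, miR-6866-5p included, had an unadjusted p under 0.05. In the authors' deposited table miR-520g-5p had a DESeq2 p of 0.0026 and miR-493-5p one of 0.017, before adjustment. Across the 461 tested miRNAs, which are not independent replicates, the fold changes of the authors' deposited table and of limma had a Spearman correlation of 0.964 and the same sign in 80.04%.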

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

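The test of how often other splits of the libraries give miRNAs on 1 side was chosen after the result was seen. Below the filter of the comparison, 4 miRNAs were listed above 0 in all 3 TENT2sh libraries and at 0 in all 3 Ctrlsh libraries, and such a signal above the level of the controls, outside the tested values, is why they are given here. miR-6866-5p averaged 0.873 RPM in TENT2sh, miR-193b-3p 0.345 RPM, miR-522-3p 0.285 RPM and the epithelial marker miR-200a-5p 0.222 RPM. Their values rest on few reads: 14, 18 and 10 implied reads for miR-6866-5p and 3, 2 and 6 for miR-200a-5p in TENT2sh 1, 2 and 3. In the opposite direction, miR-520g-5p, miR-3654 and miR-3165-5p were listed above 0 in all Ctrlsh libraries and at 0 in all TENT2sh libraries.

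For these miRNAs of 1 group only, a fall of the whole cluster around miR-520g-5p is argued against by its neighbours: 5 other members of the chromosome 19 cluster at 1 RPM or more had a median log2 ratio of TENT2sh to Ctrlsh of -0.13, within -0.25 to 0.26. They come from other hairpins and cannot decide on a change of this hairpin alone. Its other arm, in a row shared with miR-520h, was listed in all 6 libraries but low, at 0.458 RPM in Ctrlsh and 0.538 RPM in TENT2sh. miR-522-3p, listed only in TENT2sh, is a member of the same cluster and went the opposite way. All 57 rows of the cluster other than miR-520g-5p summed to 21.0 ± 3.61 RPM in Ctrlsh and 20.8 ± 3.33 RPM in TENT2sh (SD, n = 3). Pieces of the TENT2 shRNA counted as miR-6866-5p are argued against by sequence: the longest run shared by the 5' side of its hairpin and TENT2 transcripts on either strand was 9 bases, equal to the median of 829 other hairpins, whose 95th percentile was 11. Presence by chance in a table that does not list single reads stays open. Of the 10 splits of the 6 libraries 4 gave at least the 7 miRNAs of the real split, the highest other 15, but those others put both replicate 3 libraries on 1 side. Of the 4 splits that part all 3 pairs the real one gave the most, with 5 in the highest other, and with at least 10 implied reads in each of the 3 libraries it gave 2 against 0 in the highest other. These 4 splits are too few for a share under 0.05. An effect of TENT2 on these single miRNAs also stays open. The main comparison did not call miR-520g-5p (limma adjusted p = 0.081), and its filter left the others out. With no filter limma called 0 miRNAs (lowest adjusted p = 0.126), while the authors' deposited table called miR-6866-5p (DESeq2 adjusted p = 0.012).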

How the results depend on the processing

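The batch term for replicate 3, the fits without replicate 3 in both groups and the set tests with the block were chosen after seeing the data. The count of 0 miRNAs past the threshold became 1 with log2(RPM + 0.5) and 1 with array weights (miR-520g-5p in both), and 2 with the replicate 3 libraries as a batch term (miR-520g-5p and miR-29b-3p). The count of 0 hairpins became 1 with array weights (miR-450b). The count of 0 lists became 1 with the batch term and 1 without replicate 3 in both groups (endothelial-mesenchymal transition and fibrosis in both), and 2 with fry and the replicate block (that list and the miR-29 family), where camera with an estimated correlation and the block gave 0 (adjusted p = 0.800 for both lists). All members of the miR-29 family belong to the other list too, so these 2 calls are not separate. Fry asks whether members differ from 0, while camera sets them against the other miRNAs. Fry was run on the RPM scaling only, so the general shift under that scaling can enter its calls. The 1 call of the authors' deposited table became 0 at an adjusted p under 0.01 and stayed 1 with an absolute log2 fold change of at least 1. For each of these changes the cause was not tested, though the median half-width of the 95% interval went from 1.58-fold to 1.20-fold with the block. The count at an unadjusted p under 0.05 was 2 miRNAs, against 51 with the block, 58 with the batch term, 56 without replicate 3 in both groups, 39 with array weights, 11 of 911 with no filter and 0 of 218 at 10 RPM or more. With the replicate block the counts were 0 miRNAs, 0 hairpins and, by camera, 0 lists, and apart from the fry calls and the calls of miR-29b-3p adjusted over a list alone, it changed no other call. Leaving out each library in turn gave 0 miRNAs, 0 hairpins and 0 lists past the threshold each time. Without any 1 of the Ctrlsh libraries, however, miR-520g-5p fell below the filter and could not be called. In 1638 recomputed values of 87 named miRNAs, hairpins and lists, 1630 kept their side of the threshold, 8 passed it in the direction they had before and 0 reversed past it. The adjusted p of the endothelial-mesenchymal transition list ran from 0.0126 to 0.995 over its settings, that of miR-29b-3p from 0.036 to 1 and that of miR-520g-5p from 0.00086 to 0.549. Count models (edgeR, DESeq2), planned for the case that reads could be recovered, were not run. Near 1 RPM a library holds 11 to 17 reads, which limits those miRNAs, and without the block the spread of replicate 3 limits abundant ones.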

Other observations

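Tests of depth and of precursor transcription, and the contrast of replicate 3 with the other replicates, were chosen after the result they bear on was seen. The replicate 3 libraries differed from the others in single miRNAs, in both groups. Among miRNAs averaging at least 100 RPM, the 6 with the largest shift in each direction were as follows. Lower in replicate 3 were miR-99b-5p (4.49-fold, 2644 against 586 RPM), miR-125a-5p (2.75-fold), miR-423-5p (2.98-fold), miR-342-3p (2.90-fold), miR-103a/107 (2.75-fold) and let-7d-5p (2.69-fold). Higher in replicate 3 were miR-30b/30c (3.97-fold), miR-106a/17 (3.22-fold), miR-27a/27b (2.81-fold, 4387 against 12280 RPM), miR-374a-3p (2.32-fold), miR-101-3p (2.26-fold) and miR-222-3p (2.20-fold). Below that level miR-19b-3p (5.59-fold), miR-19a-3p (5.47-fold) and miR-148b-3p (4.85-fold) were higher in replicate 3 by more. In limma with group as a term 94 of the 294 miRNAs past the threshold differed at least 2-fold, and 75 of 103 hairpins had a changed arm ratio. miR-24-3p was listed at 0 in the 4 libraries of replicates 1 and 2, while miR-24-2-5p, from the opposite arm of 1 of its precursors, was listed in all 6 libraries (1.25 RPM on average in replicates 1 and 2, 5.86 RPM in replicate 3), as were its cluster partners miR-23a/23b (2267 and 4313 RPM) and miR-27a/27b. At 0.5 RPM or more, 4 miRNAs were listed only in replicate 3 and 4 only in replicates 1 and 2.

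For the replicate 3 shift, lower depth is argued against, since the replicate 3 totals were 1.05 and 1.25 times the highest other total of their group. Different transcription of the precursors as the only source is argued against too. The 5p and 3p arms of 103 hairpins should then shift together with a Spearman correlation above 0.7, a bound set after the result was seen. The correlation was 0.195 (95% bootstrap interval -0.011 to 0.382). An effect on single arms beside transcription, or noise in arms of low level, would also lower this value. A part played by transcription therefore stays open. Base composition went with the shift in a test that could have come out otherwise: GC content of the hairpin side that holds the miRNA had a Spearman correlation of -0.406 with the shift in Ctrlsh and -0.405 in TENT2sh over 398 miRNAs (86.3% of those tested), and the median shift was 0.32 in the third with the lowest GC content and -0.43 in the third with the highest. The correlation is moderate, so base composition leaves much of the shift without an account. GC content was not compared between the arms of a hairpin, so the weak agreement of the arms was not weighed against base composition. A difference in library preparation between replicate 3 and the rest remains a candidate explanation that was not tested, and the labels give no batch. Apart from precursor transcription no biological explanation was tested, since the labels give replicate 3 no other property.

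The block raised the number of miRNAs with an unadjusted p under 0.05 to 51, against 23.1 expected. Of the 4 splits that part all 3 pairs, 1, the real one, gave as many, and the highest other gave 19, but 4 splits are too few for a share under 0.05. A small difference along the replicate 3 axis cannot be told apart from an effect of the knockdown: over 461 miRNAs the group difference in replicates 1 and 2 correlated with the replicate 3 shift at 0.282 (95% bootstrap interval 0.165 to 0.404), which spans the bound of 0.3 set beforehand, and at 0.694 in the 107 miRNAs with at least 100 RPM. On the first principal component, where Ctrlsh 3 and TENT2sh 3 scored 11.9 and 11.1, TENT2sh 1 and 2 scored -4.80 and -4.97 and Ctrlsh 1 and 2 scored -6.51 and -6.71. miR-29b-3p and miR-23a/23b were higher in replicate 3 and higher in TENT2sh in 3 of 3 pairs. In pair 3, however, TENT2sh 3 scored lower than Ctrlsh 3, so the axis alone would place them lower in TENT2sh 3. There miR-29b-3p measured 8286 RPM in Ctrlsh 3 and 9567 RPM in TENT2sh 3, and miR-23a/23b 4052 and 4575 RPM. Similarity to replicate 3 may thus play a part in the small differences of abundant miRNAs in replicates 1 and 2. It does not account for the difference of these miRNAs in pair 3.

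For the counts of the comparison itself, the other splits decide nothing: the real counts are 0, which every split reaches by construction, and 10 splits of the 6 libraries are too few for a share under 0.05. All 10 splits gave at least the 0 miRNAs of the real split, with 1 in the highest other. All 10 gave at least its 0 lists, with 1 in the highest other, and all 10 at least its 0 hairpins, with 0 in the highest other. Splits that put both replicate 3 libraries on 1 side gave up to 136 miRNAs with an unadjusted p under 0.05 against 2 in the real split, which points to the structure of the samples described above.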
